A study of Mus musculus with 52 samples.

How the data were processed

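The series measured poly-A RNA in brain tissue of mice lacking the microRNA gene Mir146, which encodes miR-146a (KO), and of wild-type mice (WT). The 52 libraries form 14 groups by genotype, age and region: whole cortex at embryonic day 14 (E14; 5 KO and 4 WT), the amygdala, frontal cortex and hippocampus at postnatal day 30 (P30; 4 KO and 4 WT in each region) and the same 3 regions at postnatal day 60 (P60; 4 KO and 3 WT in the amygdala and in the frontal cortex, 2 KO and 3 WT in the hippocampus). Per the labels' protocols, the libraries were stranded and sequenced as read pairs. The growth protocol in the labels describes a human neural stem cell line and was not used, since every sample is labelled as mouse brain. The design text of the series names a sensory cortex and a sixth postnatal day where the sample labels name frontal cortex and P60, and the sample labels were followed. Per the series' design text the animals of a genotype had different mothers.

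The authors deposited 3 tables, 1 for each age, of normalised values per gene: CPM on an effective library size, with a scaling of each library that the sources used here do not state. Per the submitters' processing notes limma, DESeq, edgeR and the mouse build mm9 were used, with no role given. The aligner, the counting program and the gene annotation are not given in the sources used here, so whether counting used the strand is open. Column totals ran from 945861 to 1039135, so the values are not plain CPM. In every library each value above 0 was a whole multiple of a single step, within 0.1 read, for 100.0% of values, which gave back whole reads. Recovered depth was 8079912 to 9469214 reads per library at E14, 2933026 to 8141105 at P30 and 5322181 to 7379353 at P60. Each table listed 48526 gene IDs, of which 48058 were found by ID in the GENCODE M21 annotation of GRCm38; positions are from that annotation and not from mm9. In the E14 table the headers of the symbol and name columns were exchanged, and symbols were taken from the annotation.

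Because the values are normalised, the count test planned first was replaced by the planned fallback, limma-trend (limma 3.58.1 in R 4.3.3, with trend and robust variance) on log2(value + 1). A fold change is therefore on the log2(value + 1) scale, which understates changes of low genes. All groups of an age entered the same fit, with a contrast of KO minus WT in each region, and p-values were adjusted by Benjamini-Hochberg with a threshold of 0.05. A gene was tested when it reached 10 reads at the median depth in as many libraries as the smallest group and 15 reads over all libraries of the table. Tests were made within a table, since the tables were normalised separately. Differences between ages used recovered reads scaled together by a trimmed mean of M-values, computed in R. The tests, the gene lists, the rule for the genes named and the other settings to be tried were fixed before the data were examined, except where they are said to have been added or changed later. The rule took, for each comparison, called genes with a mean of at least 1 whose KO and WT libraries did not overlap, up to 10 in each direction, left out unnamed gene models unless among the 3 largest, and always took Mir146, Traf6 and Irak1, with Irak2, Notch1 and Numb beside the reported targets; for an interaction it took up to 5 genes. Other genes named were chosen after their values were seen. The values of 2 genes that the rule takes are not reported here.

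There were 41 gene lists of cell types, regions, pathways and signs of RNA quality. Lists with at least 3 tested members were tested with limma's camera at a preset correlation of 0.01, again with an estimated correlation, and with fry. Sites for the miR-146a seed (AGTTCTC or GTTCTCA) were searched in annotated 3′ untranslated regions of 21014 genes, and the shift of genes with a site was ranked among 200 control motifs. The rank was fixed in advance without a side; a first version on absolute differences was run and seen, and was replaced by the one-sided rank because the control motifs were not centred on 0. Similar transcripts were found with blastn 2.17.0. Sex was read from Xist and Y-linked genes; the same animal number gave the same sex in every region it appeared in (15 of 15 numbers), so samples of an age may share animals across regions.

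Shared replicate numbers of KO and WT were checked by the correlation of deviations from group means. The numbers were taken to pair the samples in the P60 amygdala alone, where the 3 pairs had correlations of 0.21 to 0.32. In the P60 hippocampus the correlations were 0.50 and 0.62, over 2 pairs, too few to judge. Numbers shared by KO and WT at P60 also had the same sex in both, so sex may give part of these correlations. In the P60 amygdala they were 0.157 to 0.311 without genes of the X and Y chromosomes. If a number is the same animal in each region, a true pairing would hold in all of them, which the other regions at P60 do not settle. The pairing comes from the data and not from the labels. Among 74 pairs of libraries of a group, none held identical values and the chi-square per gene ran from 2.31 to 23.7, so no library was counted as a repeat. p-values measure the spread between these samples.

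The test was run on simulated reads with 200 genes changed in each comparison. They were drawn from the real depths and a single mean per gene over the libraries of an age. Simulated genes and libraries varied independently, without regions or other structure of the samples. More genes were changed than were called in the real data, so the rates below may not hold there. For a simulated E14 cortex (18444 genes), 90 of 100 genes changed 2-fold and 95 of 100 changed 4-fold were called, with 4.6% false calls. For a simulated P60 hippocampus (19170 genes) these were 69 and 85 of 100, with 9.4% false calls. The alternatives were other scalings, voom on recovered reads, other filters, pseudocounts and thresholds, fits of the compared groups alone, a replicate block, a sex covariate, a residual component, and leaving out each replicate. Fits of the called lists without each replicate were added after the data were seen. Reads are not independent molecules, so depth limits cover counting error only. No column of the tables was left out.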

Results

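RNA was sequenced from the brains of mice without miR-146a, a microRNA that lowers signalling to NF-kB, and from wild-type mice. The title of the series places the work in brain development. Values are normalised read counts (CPM on an effective library size), given as mean ± SD over the libraries of a group. The comparison of KO with WT was made in 7 settings: the E14 cortex (5 KO, 4 WT), and the amygdala, frontal cortex and hippocampus at P30 (4 KO, 4 WT each) and P60 (4 KO and 3 WT, 4 KO and 3 WT, and 2 KO and 3 WT). Depth ran from 2933026 to 9469214 recovered reads per library.

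The targeted gene was examined first. Mir146 (ENSMUSG00000065601; chromosome 11, 43374397 to 43374461, GRCm38) had 1 read in 1 of the 52 libraries, a WT hippocampus at P30, and none in the others. A poly-A library does not capture a mature microRNA, so this gene does not check the genotype labels. Traf6, a ubiquitin ligase, and Irak1, a kinase, both of innate immune signalling and reported miR-146a targets, did not pass the test in any setting. In the E14 cortex Traf6 was at 72.2 ± 3.07 in KO and 72.1 ± 5.16 in WT (limma adjusted p = 1.00), and Irak1 was at 48.7 ± 2.12 and 48.9 ± 3.91 (limma adjusted p = 1.00).

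In the E14 cortex 9 of 18350 genes were called, 3 higher and 6 lower in KO (limma, n = 5 KO and 4 WT). Pttg1 (ENSMUSG00000020415), which encodes securin, the inhibitor of sister chromatid separation, rose from 3.74 ± 1.05 in WT to 21.4 ± 5.47 in KO, 5.72-fold (log2 fold change 2.23, SE 0.196, limma adjusted p = 0.00101). Lyrm7 (ENSMUSG00000020268), a chaperone of mitochondrial complex III assembly, rose from 7.48 ± 0.859 to 16.9 ± 1.06, and the processed pseudogene Gm5913 from 1.64 ± 0.0718 to 6.25 ± 0.969. Lmx1b, a homeobox transcription factor (chromosome 2, 33560965 to 33640511) fell 14.5-fold, from 6.36 ± 2.87 to 0.438 ± 0.452 (230 and 19 reads in all). The forkhead transcription factors Foxa1 and Foxb1 fell, Foxa1 from 6.64 ± 1.41 to 0.924 ± 0.791 and Foxb1 from 6.65 ± 2.36 to 0.926 ± 0.66. Ttc6, beside Foxa1 on chromosome 12, and C130021I20Rik, an antisense RNA beside Lmx1b on chromosome 2, also fell, by 1.59 and 1.93 on the log2 scale. Foxb1 overlaps the antisense gene B230323A14Rik, and Gm5913 is 98.0% identical over 1399 bases to G3bp1, so reads of both may be shared with those genes. Genes of the thalamus, habenula and hypothalamus lists also lay lower in KO (17 of 20 tested, median -0.31, and -0.18 without KO replicate 5). These lists were fixed for the postnatal ages and were read at E14 only after the results were seen. As 1 list they had adjusted p = 0.148 by camera with an estimated correlation, and fry gave 0.24. Calls ended without KO replicate 4 or WT replicate 3, each leaving 5 called genes: for Lmx1b without these 2 (adjusted p up to 0.0815, limma), for Foxa1 without these, KO replicate 1 or any other WT replicate (up to 0.108), for Foxb1 without these, KO replicate 2 or WT replicates 1 or 4 (up to 0.148), and for Ttc6 without these, KO replicates 1 or 5 or WT replicate 1 (up to 0.128). With a pseudocount of 0.1 the calls of Lmx1b, Foxa1 and Foxb1 ended (adjusted p from 0.212 to 0.364, limma), and with voom those of Lmx1b, Foxa1, Foxb1 and Ttc6 (up to 0.14, limma).

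**Figure D1:**
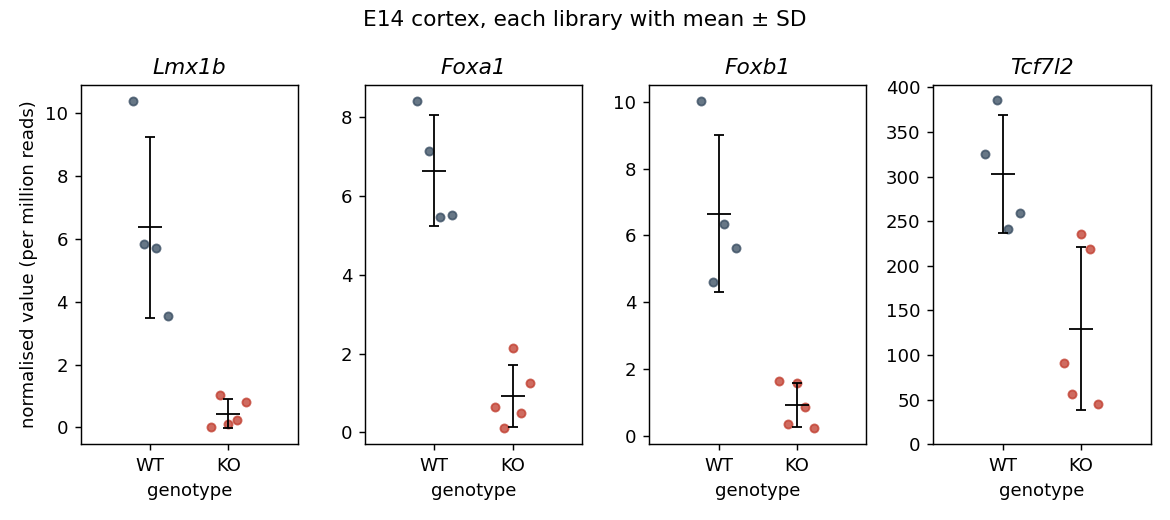
Normalised read counts in CPM (vertical axis) of Lmx1b, Foxa1, Foxb1 and Tcf7l2 in each E14 cortex library of WT and KO (horizontal axis), with mean and SD as bars; Tcf7l2 was chosen after its values were seen. For Lmx1b the WT mean was 6.36 and the KO mean 0.438, and for Tcf7l2 303 and 129.

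Among the lists fixed for E14, 11 of 24 were called at the preset correlation and none with an estimated one; 3 of the 11 (interferon-stimulated, mitochondrially encoded and Cajal-Retzius genes) kept the call without each replicate in turn. Those fits of lists, here and in the later settings, were added after the data were seen. All 9 tested interferon-stimulated genes had a KO mean above WT (median log2 fold change 0.32), with adjusted p = 0.494 with an estimated correlation. The 13 mitochondrially encoded genes lay above 0 (median 0.13, 1 gene adjusted over the list alone, mt-Rnr1), with adjusted p = 0.284 with an estimated correlation. Cajal-Retzius cell genes lay lower (7 of 8, median -0.36, 2 adjusted over the list alone, Ebf3 and Lhx1), with adjusted p = 0.494 with an estimated correlation. Their median was -0.15 without KO replicate 5, whose score stood far below the others (mean z -1.88), and -0.22 without WT replicate 3. Lists of neighbouring tissue lay lower without being called: cortical hem and choroid plexus genes (6 of 9, median -0.21, camera adjusted p = 0.0692) and meningeal genes (9 of 10, median -0.21, camera adjusted p = 0.159), each with adjusted p = 0.64 with an estimated correlation. The scores of KO and WT libraries overlapped for both. Neither list was fitted without each replicate, so a single library may carry these differences. Of 12 deep-layer neuron genes 8 lay higher (median 0.29, Tbr1 called adjusted over the list alone), with adjusted p = 0.494 with an estimated correlation. Their median was 0.18 without KO replicate 5, and the call ended without KO replicate 4 (0.22) or WT replicate 3 (0.17). Of 20 Notch pathway genes 18 lay lower (median -0.10), with adjusted p = 0.64 with an estimated correlation. The call ended without KO replicate 4 (median -0.02), KO replicate 5 (-0.03) or WT replicate 4 (-0.05), and the median was -0.18 without KO replicate 2 or 3 and -0.20 without WT replicate 1. The 19 cell cycle genes all lay below 0 (median -0.11), with adjusted p = 0.64 with an estimated correlation. Their median turned to 0.02 without KO replicate 4 and to 0.00 without KO replicate 5, the call also ended without WT replicates 2 (-0.08) or 4 (-0.05), and the median was between -0.18 and -0.21 without KO replicates 1, 2 or 3 or WT replicate 1. The other lists called were glutamate receptor genes (20 of 23 higher, median 0.10), ribosomal proteins (28 of 34 higher, 0.06), microglial genes (9 of 12 higher, 0.16), complement and antigen presentation genes (5 of 7 higher, 0.23) and ganglionic eminence genes (12 of 16 lower, -0.09), with adjusted p from 0.494 to 0.64 with an estimated correlation. Each of these 5 lost its call in 3 to 5 of the 9 fits, each of the 9 libraries ended at least 1 of them. Glutamate receptor genes lost the call without KO replicates 4 (0.04) or 5 (0.03) or WT replicates 2 (0.09) or 4 (0.08), and were at 0.18, 0.16 and 0.17 without KO replicate 2, KO replicate 3 or WT replicate 1. Ribosomal proteins lost it without KO replicates 1 (0.07), 2 (0.04) or 3 (0.01) or WT replicates 1 (0.04) or 3 (0.03), and were at 0.11 and 0.09 without KO replicate 5 or WT replicate 4. Microglial genes lost it without KO replicates 4 (0.09) or 5 (0.11) or WT replicates 1 (0.12) or 3 (0.12), and complement genes without KO replicates 3 (0.17) or 4 (0.21) or WT replicate 3 (0.18). Ganglionic eminence genes lost it without KO replicates 2 (-0.01) or 4 (0.01) or WT replicates 1 (-0.03) or 3 (-0.03), and were between -0.14 and -0.17 without KO replicates 1 or 3 or WT replicates 2 or 4. Of 19 tested reported miR-146a targets none was called over all genes and 1, Nova1, was called adjusted over the list alone (median -0.02). The target list was not called by camera in any setting. Its median at P30 was -0.002 in the amygdala, 0.03 in the frontal cortex and -0.05 in the hippocampus. Irak2, Notch1 and Numb were not called over all genes in any setting; at E14 Notch1 was at 228.5 ± 63.9 in KO and 254.8 ± 17.8 in WT. The embryos were 2 female and 3 male in KO and 3 female and 1 male in WT. WT replicate 3 had the lowest score of its group for mitochondrially encoded genes (mean z -0.977).

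**Figure D2:**
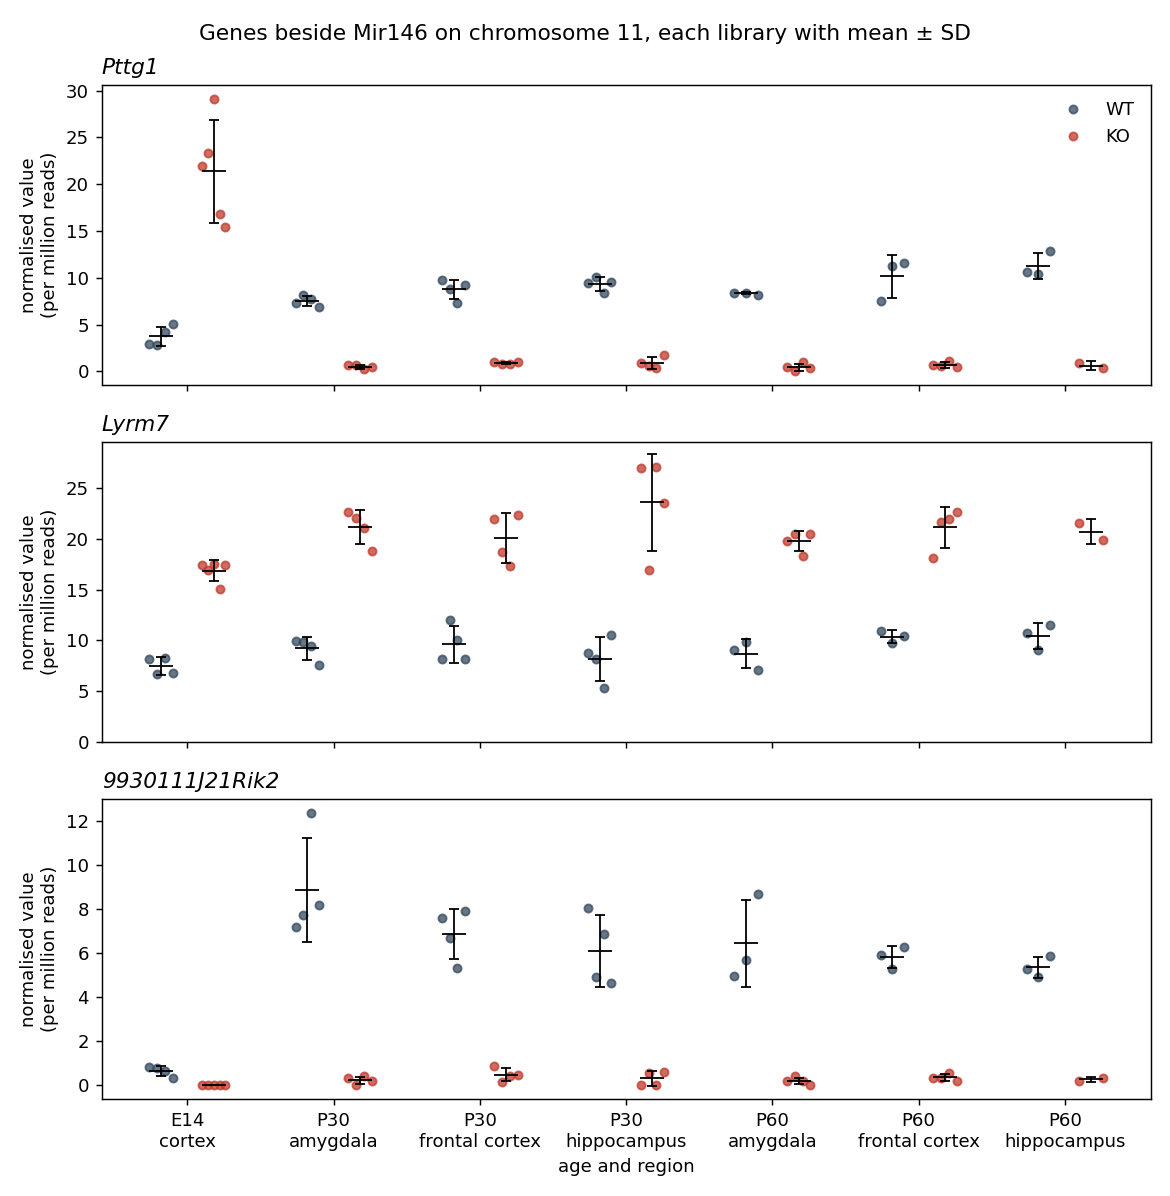
Normalised read counts in CPM (vertical axis) of Pttg1, Lyrm7 and 9930111J21Rik2 in each library of WT and KO, by age and region (horizontal axis), with mean and SD as bars. Pttg1 was higher in KO at E14 (21.4 against 3.74) and lower in the 6 later settings, and Lyrm7 was higher in KO in all 7.

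In the P30 amygdala 5 of 18976 genes were called (limma, n = 4 and 4). Pttg1 fell from 7.54 ± 0.544 in WT to 0.505 ± 0.198 in KO, 14.9-fold (log2 fold change -2.51, SE 0.17, limma adjusted p = 1.1e-09), opposite to E14. 9930111J21Rik2, a gene of unnamed function, fell from 8.87 ± 2.38 to 0.203 ± 0.165, and Gm2a, the GM2 ganglioside activator, from 73.4 ± 7.18 to 54.3 ± 1.67. Lyrm7 rose from 9.22 ± 1.13 to 21.1 ± 1.67 and Hint1, a purine phosphoramidase, from 54.9 ± 1.61 to 76.9 ± 2.78. 9930111J21Rik2 is 99.0% identical over 3221 bases to 9930111J21Rik1, so its reads may be split between the copies. Gm2a lost its call without any of the replicates except WT replicate 2 (7 of 8 fits, adjusted p up to 0.256, limma), and with a sex covariate (0.187).

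Glial genes lay lower in KO amygdala at P30. All 18 microglial and macrophage genes were below WT (median log2 fold change -0.32), 9 adjusted over the list alone, among them Csf1r, P2ry12 and Cx3cr1; adjusted p = 0.112 with an estimated correlation, and fry gave 0.0243. All 15 astrocyte genes were below WT (median -0.21), 5 adjusted over the list alone, among them Gfap and Apoe; adjusted p = 0.112 with an estimated correlation, and fry gave 0.0243. Of 13 mitochondrially encoded genes 12 lay lower (median -0.28, 8 adjusted over the list alone), with adjusted p = 0.23 with an estimated correlation. Choroid plexus genes lay lower too (13 of 13, median -0.75), with adjusted p = 0.534 with an estimated correlation. Without WT replicate 1, whose score was 1.52, their median was -0.10 and the call ended. In all, 14 of 32 lists were called at the preset correlation, and 7 kept the call without each replicate in turn. Those 7 were microglia, astrocytes and mitochondrially encoded genes, with complement and antigen presentation genes (11 of 11 lower, median -0.30), oligodendrocyte precursor genes (11 of 11 lower, -0.31), Notch pathway genes (18 of 20 lower, -0.12, Notch1 and Maml1 called adjusted over the list alone) and excitatory neuron genes (8 of 12 higher, 0.24), with adjusted p from 0.112 to 0.388 with an estimated correlation. WT replicate 3 had the highest microglial score of the group (mean z 2.17) and was the only postnatal library not highest for the list of its own region. Without it the microglial median was -0.23 and the complement median -0.18, and the Notch median was -0.21 without KO replicate 2 and -0.19 without WT replicate 2. Without WT replicate 3 the calls of 4 further lists ended and their medians went from -0.52 to -0.12 (16 myelin genes), from -0.30 to -0.09 (20 interferon-stimulated genes), from -0.25 to -0.08 (15 endothelial genes) and from 0.25 to 0.14 (13 GABA receptor genes), with adjusted p from 0.356 to 0.484 with an estimated correlation in all libraries. The thalamus list (10 of 11 lower, median -0.22) lost its call in 4 of 8 fits and glutamate receptor genes (16 of 23 higher, median 0.06) in 5, with adjusted p = 0.388 and adjusted p = 0.585 with an estimated correlation. These calls ended without KO replicates 1 or 3 or WT replicates 1 or 3 (thalamus, median from -0.26 to -0.18) and without KO replicates 2, 3 or 4 or WT replicates 1 or 3 (glutamate receptors, 0.03 without WT replicate 3 to 0.10 without KO replicate 4); the latter median was also 0.10 without KO replicate 1, with the call kept. In fits without WT number 3 in the 3 regions, added after the data were seen, 25 genes were called in the amygdala. The sexes differed, with 3 female and 1 male KO and 1 female and 3 male WT animals at P30.

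**Figure D3:**
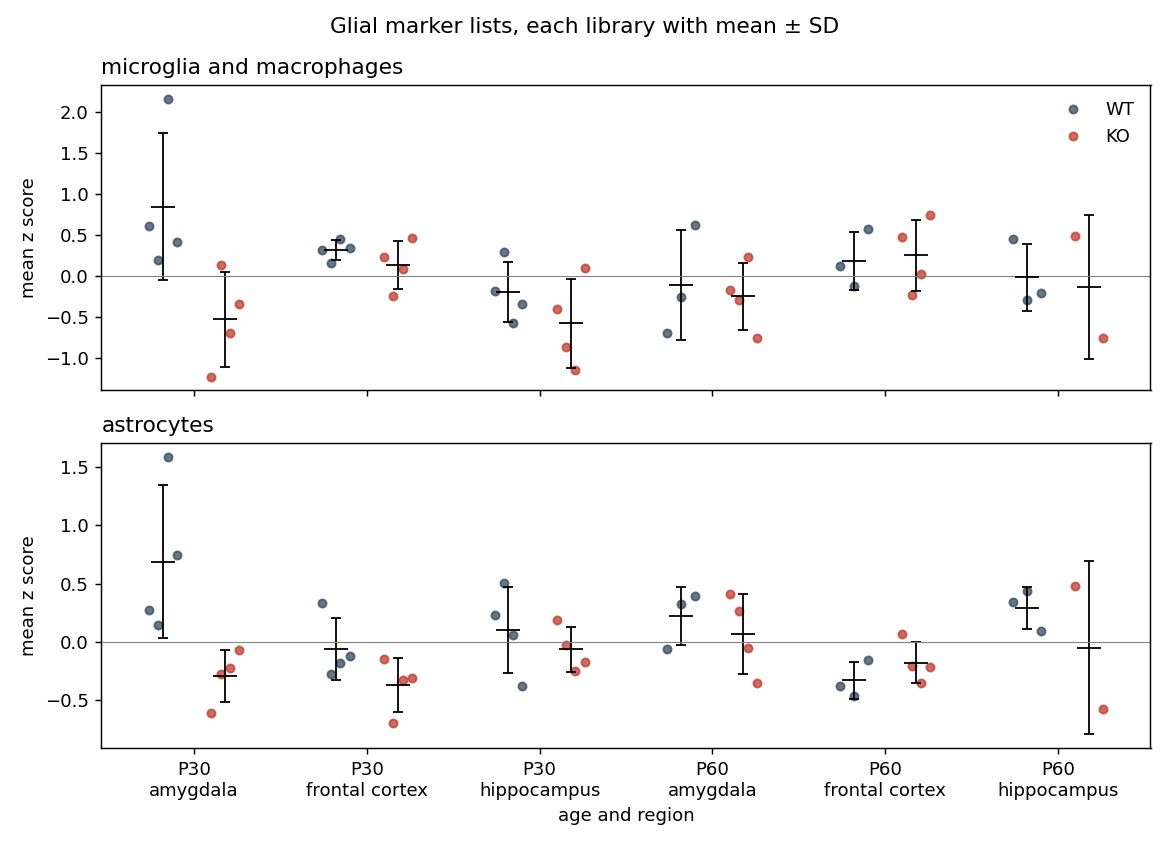
Mean z score (vertical axis) of the microglia and astrocyte lists in each postnatal library of WT and KO, by age and region (horizontal axis), with mean and SD as bars. In the P30 amygdala a single WT library stands at 2.17 for microglia and 1.59 for astrocytes.

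In the P30 frontal cortex 3 of 18976 genes were called (limma, n = 4 and 4): Lyrm7 rose (9.61 ± 1.8 to 20.1 ± 2.48), and Pttg1 (8.79 ± 1.02 to 0.875 ± 0.121) and 9930111J21Rik2 (6.87 ± 1.16 to 0.445 ± 0.299) fell. Lyrm7 lost its call without KO replicates 1 or 4 or WT replicates 1 or 4 (adjusted p up to 0.11, limma) and with a sex covariate (0.0612). Of 18 immediate early genes 17 lay higher (median 0.25), the only list of 32 called, with adjusted p = 0.982 with an estimated correlation; the call ended without WT replicate 2 (median 0.03), KO replicate 3 (0.18) or KO replicate 4 (0.17).

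In the P30 hippocampus 6 of 18976 genes were called (limma, n = 4 and 4). Lyrm7 rose 2.88-fold (8.2 ± 2.16 to 23.6 ± 4.76), and Pttg1 fell from 9.35 ± 0.725 to 0.89 ± 0.617 and 9930111J21Rik2 from 6.09 ± 1.63 to 0.283 ± 0.326. Cdc42se2, an effector of the GTPase Cdc42, fell from 89.3 ± 10.2 to 58.2 ± 3.72, Gm2a from 69.1 ± 6.76 to 45.7 ± 4.36, and Elfn1, a postsynaptic protein of interneuron synapses, from 41.9 ± 5.23 to 28.0 ± 3.06. Of 32 lists 4 were called. All 16 myelin genes lay lower (median -0.77, and -0.505 without WT replicate 3), with adjusted p = 0.812 with an estimated correlation. All 11 oligodendrocyte precursor genes lay lower (median -0.39), 7 adjusted over the list alone, among them Pdgfra, Cspg4 and Olig2, with adjusted p = 0.458 with an estimated correlation; the median was -0.64 without WT replicate 1. Of 15 hippocampal neuron genes 11 lay higher (median 0.42), with adjusted p = 0.812 with an estimated correlation. Of 12 excitatory neuron genes 10 lay higher (median 0.22), with adjusted p = 0.838 with an estimated correlation. Without WT replicate 3, whose hippocampal neuron score was 0.0251 and the lowest of the group, both calls ended and the medians were 0.23 and -0.01. The hippocampal neuron median was 0.25 without KO replicate 1, and the excitatory neuron call also ended without KO replicates 1 (0.18) or 3 (0.22). All 13 choroid plexus genes lay lower (median -0.68) and the list was not called (camera adjusted p = 0.0659, and adjusted p = 0.838 with an estimated correlation). WT replicate 3 had a choroid plexus score of 3.11 and the list was not fitted without it. That library may carry this difference. Without WT replicate 1, 266 genes were called, 195 of them lower in KO; without WT replicate 3, whose choroid plexus score was 3.11, 12 were called, and without KO replicate 4, 11. Elfn1 lost its call without KO replicates 1 or 2 or WT replicate 2 (adjusted p up to 0.144, limma), and 2 genes were called in a fit of these 8 libraries alone.

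In the P60 amygdala 4 of 19239 genes were called (limma, n = 4 and 3). Lyrm7 rose from 8.68 ± 1.43 to 19.8 ± 1.01, Pttg1 fell from 8.33 ± 0.108 to 0.438 ± 0.403, 9930111J21Rik2 from 6.44 ± 1.99 to 0.17 ± 0.152 and Kif3a, a motor subunit of ciliary transport, from 206 ± 8.43 to 155 ± 6.53. With the replicate block, which fits the pairing there, the log2 fold change of Kif3a was -0.39 (SE 0.068, limma adjusted p = 0.113) and 3 genes were called. Kif3a also lost its call without any of the replicates except KO replicate 2 (adjusted p up to 0.399, limma). Of 32 lists 5 were called, and 6 with the replicate block, the same 5 and the glutamate receptor list. The list values given here are from the fit without the block. Each of the 5 lost its call in 3 or 4 of the 7 fits without a replicate. Of 10 hypothalamic genes 8 lay higher (median 0.62), with adjusted p = 0.734 with an estimated correlation. This call ended without KO replicates 1 (0.52) or 3 (0.28) or WT replicate 3 (0.10), and the median was 0.96 without KO replicate 2 and 0.41 without KO replicate 4. All 12 meningeal genes lay higher (median 0.26), with adjusted p = 0.734 with an estimated correlation. That of the meninges ended without KO replicates 1 (0.05) or 2 (0.12) or WT replicate 3 (0.16), and the median was 0.42 without WT replicate 1. Of 13 mitochondrially encoded genes 11 lay higher (median 0.14), with adjusted p = 0.734 with an estimated correlation. It ended without KO replicates 2 (0.11) or 3 (0.10) or WT replicate 1 (0.05), and the median was 0.23 without WT replicate 3. Of 12 excitatory neuron genes 10 lay lower (median -0.18), with adjusted p = 0.734 with an estimated correlation. Here it ended without KO replicates 1 (-0.26) or 3 (-0.05) or WT replicates 1 (-0.25) or 3 (-0.10), and the median was -0.27 without KO replicate 2. Of 13 complement and antigen presentation genes 9 lay higher (median 0.26, Cd74 and H2-Aa adjusted over the list alone), with adjusted p = 0.734 with an estimated correlation. The last ended without KO replicates 1 (0.15), 2 (0.20) or 3 (0.18) or WT replicate 1 (0.19).

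In the P60 frontal cortex 6 of 19239 genes were called (limma, n = 4 and 3). Lyrm7 rose from 10.4 ± 0.637 to 21.1 ± 2.02, Tnip1, an inhibitor of NF-kB signalling, from 21.4 ± 2.15 to 36.8 ± 2.81, and the pseudogene Olfr1372-ps1 from 0.0467 ± 0.0808 (1 read in 3 libraries) to 1.77 ± 0.413. Pttg1 fell from 10.2 ± 2.26 to 0.688 ± 0.292, 9930111J21Rik2 from 5.81 ± 0.496 to 0.325 ± 0.167 and Kif3a from 172 ± 9.84 to 130 ± 4.6. Kif3a lost its call without any replicate except KO replicate 3 (adjusted p up to 0.335, limma), Olfr1372-ps1 without any except KO replicate 2 (up to 0.203), and Tnip1 without WT replicate 1 (0.0691), which left 3 called genes. Of 32 lists 3 were called: 16 of 20 interferon-stimulated genes lay higher (median 0.19), with adjusted p = 0.896 with an estimated correlation. The call ended without KO replicate 4 (0.14), and the median was 0.12 without KO replicate 3. Of 14 clock genes 12 lay higher (median 0.16), with adjusted p = 0.896 with an estimated correlation; the call ended without WT replicate 3 (0.06). Of 34 ribosomal protein genes 26 lay lower (median -0.07), with adjusted p = 0.904 with an estimated correlation; the call ended without KO replicate 3 (-0.04) or WT replicate 3 (-0.06). Striatal genes lay lower (11 of 13, median -0.79) without being called (camera adjusted p = 0.0612, and adjusted p = 0.904 with an estimated correlation), and their scores overlapped, from -0.634 to 1.32 in KO and from 0.497 to 1.01 in WT.

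In the P60 hippocampus 4 of 19239 genes were called (limma, n = 2 and 3). Lyrm7 rose from 10.4 ± 1.26 to 20.7 ± 1.23; Pttg1 fell from 11.3 ± 1.41 to 0.62 ± 0.438, 9930111J21Rik2 from 5.34 ± 0.478 to 0.235 ± 0.106 and Cdc42se2 from 88.7 ± 5.07 to 51.8 ± 3.4. Lyrm7 lost its call without KO replicates 1 or 2 or WT replicate 2 (adjusted p up to 0.413, limma), and Cdc42se2 without KO replicate 2 (0.15). In a limma fit of these 5 libraries alone 0 of 17343 genes were called (125 at an unadjusted p under 0.05), against 4 (392) in the fit of all P60 libraries. The calls of all 4 genes ended there, with an adjusted p of 0.112 for Pttg1 and 0.167 for 9930111J21Rik2. Of 13 mitochondrially encoded genes 11 lay lower (median -0.15), the only list of 32 called, with adjusted p = 0.949 with an estimated correlation; the call ended without KO replicate 2 (-0.06) or WT replicate 3 (-0.13).

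Whether the genotype difference depended on region or age was tested with interaction terms in limma. The fits held no term for the animal, though samples of an age may share animals across regions. The test for region may therefore miss differences within animals. No gene was called for region at P30 (871 at an unadjusted p under 0.05) or P60 (415), or for age in the amygdala (1530), frontal cortex (489) or hippocampus (838); voom on recovered reads also called 0 in each. Between the E14 cortex and the later frontal cortex, a comparison added after the data were seen, on reads scaled across tables and with a region that differs, 15 genes were called at P30 and 15 at P60. The genotype difference of Pttg1, on the log2 scale, was -4.60 (SE 0.265) at P30 minus E14 and -4.94 (SE 0.276) at P60 minus E14. The counts also include Foxa1 (1.97 at P30 and 1.97 at P60) and C130021I20Rik (1.73 and 1.79), whose differences do not tell of a dependence on age. Foxa1 had 0 reads in the frontal cortex at both ages and C130021I20Rik 3 in KO and 4 in WT at P30 and 1 in each at P60, so these values are close to the fold change at E14 with its sign turned. The count at P30 also holds 9930111J21Rik2 (-1.88), whose difference is limited by its few reads at E14. With voom 1 gene was called at each age.

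Lyrm7 was called higher in KO in all 7 settings, and Pttg1 and 9930111J21Rik2 lower in 6. At E14 9930111J21Rik2 had 0 reads in KO and 23 in WT and did not pass the filter on reads. In the fit without a filter it was called lower in KO at E14. Of the 17 genes called in any setting, 9 lay on chromosome 11 from Pttg1 (43420250 to 43426251, 45.9 kb from Mir146) to Gm2a (55098115 to 55113029, 11.7 Mb away), with Lyrm7 at 54826866 to 54860916. In the list of 40 genes flanking Mir146, 28 were tested at E14 and Pttg1 was the only member called there over all genes. As a list these genes were not called by camera in any setting (camera adjusted p = 0.387 at E14). That test looks for a shift in a single direction, and 14 of the 28 lay higher at E14, so it may miss differences both ways. Adjusted over the list alone, Gabrb2, Ccng1, Slu7 and Pttg1 were called in the P30 amygdala, and Ccng1, Slu7 and Pttg1 in the P30 hippocampus. The 8 genes called elsewhere were 7 at E14 and Elfn1 on chromosome 5 (139907943 to 139974722).

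**Figure D4:**
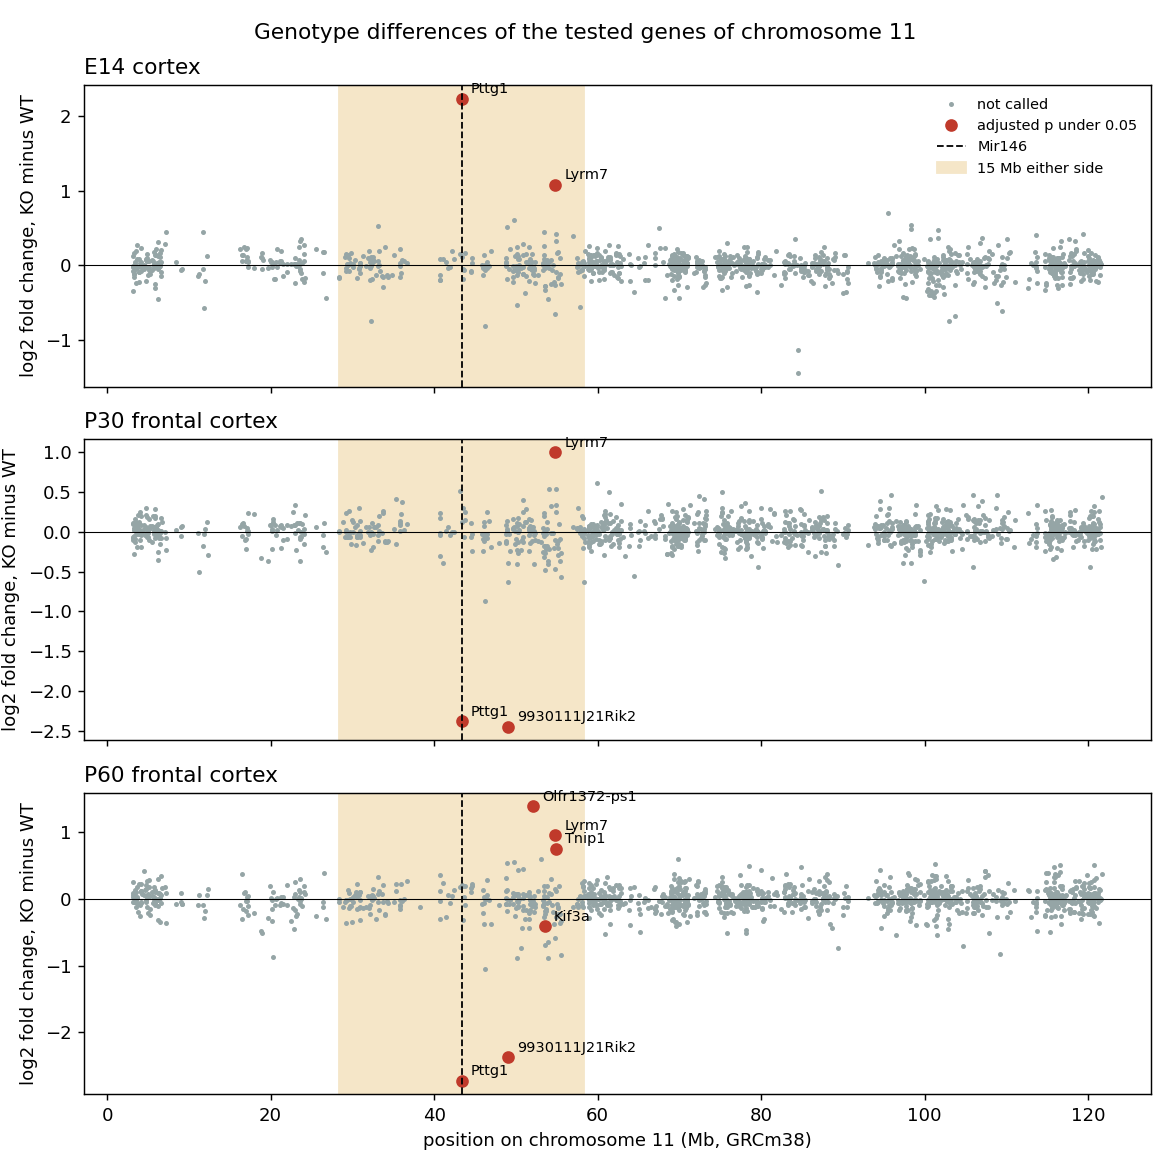
Log2 fold change, KO minus WT (vertical axis), of each tested gene by its start on chromosome 11 in Mb (horizontal axis) in the E14 cortex, P30 frontal cortex and P60 frontal cortex; large points are genes called at an adjusted p under 0.05, the dashed line is Mir146 and the shaded band covers 15 Mb on either side. The genes called there all lie inside the band, with Pttg1 at 2.23 at E14 and -2.38 at P30.

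Genes with miR-146a seed sites were compared with genes without. In no setting did their median shift upward in KO beyond the control motifs: at E14, 184 of 200 control motifs gave a difference at least as high (2853 genes with a site), and in the P30 hippocampus 41 of 200 (2976 genes). The smallest share was in the P60 frontal cortex, 29 of 200, a one-sided rank p of 0.149 among the motifs and 0.732 after adjustment over the 7 settings.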

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

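The tests of the region around Mir146, of exchanged labels, dividing cells, shared reads, dissected tissue and sex, the overlap of calls between ages as a test of chance, those without a replicate for gene lists, and the list test of the joined thalamus, habenula and hypothalamus genes, were chosen only after the results were seen; the test on thinned reads was chosen before its own result, and the counts over other splits of the libraries were planned but read before bounds were set for them.

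The genes near Mir146 differed between genotypes at all ages: within 15 Mb on chromosome 11, 28 of 224 genes (12.5%) had an unadjusted p under 0.01 at P30, in means of each animal number over regions, against 1.61% of the others (Fisher's exact p = 2.9e-16, which treats genes as independent). The excess was not even around Mir146. At 20 to 30 and 30 to 40 Mb 0 of 58 and 0 of 51 genes had such a p at P30. At 40 to 50 and 50 to 60 Mb these were 7 of 56 and 21 of 140. The called genes lower in KO there argue against lost direct repression by miR-146a, for those genes. Of the 4 searched called genes higher in KO there, Pttg1 among them through E14 alone, 0 held a seed site. Since 18.2% of all searched genes hold a site, this count by itself is weak. Indirect repression was not tested. For the opposite sign of Pttg1 at E14 (differences of -4.60 and -4.94 from the P30 and P60 frontal cortex) the tables argue against exchanged labels at E14. There 10 of 11 genes at an unadjusted p under 0.05 at all ages kept their sign. They also argue against more dividing cells, since 0 of 19 cell cycle genes were higher and their median was at most 0.02 without any 1 replicate. A candidate explanation is DNA of another strain carried beside the targeted gene: 96.4% of the 28 genes kept their sign in the P60 animals, against 32.5% of 302 genes chosen alike elsewhere. Gm5913, on chromosome 8, was higher in KO in 7 of 7 settings in which G3bp1, its parent gene in that region, was lower, which is what reads of G3bp1 assigned to its pseudogene copy would give if the KO animals carry another sequence of G3bp1. Gm5913 was called at E14 only and G3bp1 in no setting. Settings of an age may share animals, so they are not separate evidence. The strains are not in the labels, no base could be read from these tables, an effect of the deletion itself on its neighbours is a biological explanation not tested, and what sets the sign of Pttg1 stays open.

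Lmx1b, Foxa1, Foxb1, Ttc6 and C130021I20Rik were lower in KO at E14, and with sex in the fit at least 98.9% of each log2 fold change was kept, which argues against the sexes of the embryos as the whole cause. The calls of Foxb1 (log2 fold change -2.01 before, -2.0 with an SE of 0.30 after, adjusted p 0.0884) and Ttc6 (-1.59 before, -1.62 with an SE of 0.23 after, adjusted p 0.0597) ended with sex in the limma fit, where the folds stayed and the errors grew. More tissue from beneath the cortex in the WT dissections may account for the set: 20 tested genes of the thalamus, habenula and hypothalamus lists had a median of -0.31 with 17 lower, and -0.18 without KO replicate 5. As 1 list they were called by camera at the preset correlation, but not otherwise (adjusted p = 0.148 with an estimated correlation, and fry gave 0.24), so genes of a tissue that vary together limit this evidence. Tcf7l2, an abundant gene of the thalamus, was at 129 in KO and 303 in WT but was not called over all genes; all 20 passed the filter on reads in these cortex libraries as well. A change in these cells in the KO is the biological alternative, which was not tested and stays open.

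Microglial and astrocyte genes lay lower in KO in the P30 amygdala, with a microglial median of -0.32. It was -0.33 with reads thinned to the shallowest amygdala library. Thinning keeps the expected normalised value of each gene, so it could hardly move this median and does not decide on depth. With sex in the fit the microglial median was -0.29, which argues against sex as the whole cause. Without WT replicate 3, which stood highest for both lists, it was -0.23, with 17 of 18 genes lower, so a single library carries part of the difference. The other WT libraries still scored above each KO library (microglia, lowest WT 0.194 and highest KO 0.139; astrocytes, 0.141 and -0.0736). Whether the rest is beyond the spread of so few libraries stays open: without WT replicate 3 both lists were called at the preset correlation, with adjusted p = 0.208 with an estimated correlation, fry gave 0.1, and the exact rank p of the scores was 0.0571, the lowest that 4 and 3 libraries can give. A lower share of glia in the KO amygdala, or a difference in what was dissected, may remain after that value. The microglial median was -0.05 in the P30 frontal cortex and -0.09 in the P30 hippocampus. The genotype by region interaction called 0 genes at P30 (limma, with 871 at an unadjusted p under 0.05, and 0 with voom). That fit held no term for the animal and no list was tested for the interaction. It does not decide whether the glial difference is particular to the amygdala.

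Splits of the same libraries into other groups of the same sizes show how far chance can be excluded for each count. In the P60 frontal cortex the real 6 stood against at most 1 in the other splits of 35. That is the smallest share that 35 splits can give. It was read beside the other settings without adjustment, so it argues against chance for this count but does not exclude it. At E14 4 of 100 splits, the real one included, gave at least the real 9 genes. The others gave 1158, 1210 and 3110 genes, which points to a structure of the samples other than genotype. In each of them KO replicates 4 and 5 stood with WT replicate 1. KO replicates 2 and 3 stood with WT replicates 2 and 4 on the other side. Deviations from group means correlated at 0.48 and 0.57 between WT replicate 1 and KO replicates 4 and 5. What gives this structure was not tested. The split count by itself is therefore weak against chance at E14. It did not exclude chance for the P30 amygdala (2 of 35; real 5, highest other 5), the P30 frontal cortex (2 of 35; real 3, highest other 13), the P30 hippocampus (5 of 35; real 6, highest other 105) and the P60 amygdala (2 of 35; real 4, highest other 13). The 105 and the 13 genes also point to a structure of the samples. Among the 8 splits of the P60 amygdala that part 3 pairs, as the real one does, the highest other gave 2 genes. For Lyrm7, Pttg1 and 9930111J21Rik2 the animals of the other age argue against chance but do not exclude it. In the frontal cortex P30 and P60 shared 1 gene called higher and 2 called lower (Fisher's exact p = 9.2e-12, which treats genes as independent). In the amygdala they also shared 1 and 2 (p = 3.7e-11 by the same exact test). These genes all lie within 15 Mb of Mir146 and may vary together. The p-values therefore overstate the evidence and do not measure the spread between animals. For the interactions the real count is 0, which 100 of 100 splits meet by construction, so these splits say nothing of chance; the highest others were 2 for region at P30, 228 for age in the amygdala and 1 for age in the frontal cortex. Those 0 calls are from limma, with 871, 1530 and 489 genes at an unadjusted p under 0.05, and voom also called 0 in each. Between E14 and the frontal cortex 6 of 100 splits gave at least the real 15 genes at P30 (highest other 358) and 5 of 100 the real 15 at P60 (highest other 408), so chance was not excluded for these counts. No splits were run for the P60 hippocampus, which has 2 KO libraries.

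Single libraries stood far from the rest of their group in 9 of 154 groups examined, where chance gives 7.7. KO replicate 3 of the P30 hippocampus had 2933000 recovered reads, and the nearest of its group 6993000. Lyrm7 in KO replicate 4 at E14 was at 15.02, with the nearest at 16.9. Irak1 in KO replicate 3 of the P30 frontal cortex was at 48.1, with the nearest at 42.5. The mean z score of Cajal-Retzius genes was -1.88 in KO replicate 5 at E14 (nearest -0.185), and that of mitochondrially encoded genes -0.977 in WT replicate 3 at E14 (nearest -0.41). In the P30 amygdala the Notch pathway score was 0.877 in WT replicate 3 (nearest 0.306) and the choroid plexus score 1.52 in WT replicate 1 (nearest -0.252). In the P30 hippocampus the excitatory neuron score was -1.11 in WT replicate 3 (nearest 0.342) and the hippocampal neuron score 0.835 in KO replicate 4 (nearest 0.999).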

How the results depend on the processing

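The alternatives with TMM factors, plain CPM, a sex covariate, a residual component, left-out sets of libraries, other designs for the list tests and lists without each replicate, and all settings of the differences between E14 and later ages, were chosen after seeing the data. Planned DESeq2, edgeR and svaseq alternatives were not run, since the values are normalised and no separate check verified the recovered reads as counts. Other scaling factors were computed in R. At E14 a fit of the compared groups alone is the same fit. Of 823 alternatives for 37 called gene results, 100 ended the call, 0 reversed the direction, and 15 results kept their call in each alternative tried. Where 1 KO library of the P60 hippocampus was left out, the other is assumed to vary like the other groups. The cause was not tested, except that fits with fewer libraries have fewer samples. Replicate numbers were taken to pair the samples in the P60 amygdala alone. Correlations elsewhere ran from -0.40 to 0.26 at E14, and from -0.21 to 0.18, -0.16 to 0.07 and -0.01 to 0.10 in the regions at P30. They were 0.03 to 0.22 in the P60 frontal cortex. In the P60 hippocampus they were 0.50 to 0.62, over only 2 pairs, too few to judge. Depth limits low genes: 1 to 40 reads in a group stand behind the means under 1 of called genes.

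The number of called genes, without each replicate in turn, ran from 5 to 9 at E14, from 4 to 7, 2 to 3 and 5 to 266 in the P30 amygdala, frontal cortex and hippocampus, and from 3 to 5, 3 to 5 and 3 to 4 in the same regions at P60. Without KO replicate 4 or WT replicate 3 it was 5 each at E14. In the P30 hippocampus it was 11 without KO replicate 4, 266 without WT replicate 1 and 12 without WT replicate 3; without WT replicate 1 of the P60 frontal cortex it was 3. At E14 it was 5 with voom, 3 with the replicate block, 5 with a pseudocount of 0.1 and 29 with a residual component. In the P30 amygdala it was 11 with no filter, 33 with a residual component, 3 with an absolute log2 fold change of at least 0.5, 8 without the P30 libraries of low depth and 25 without WT number 3. In the P30 frontal cortex it was 5 with no filter and 5 without WT number 3. In the P30 hippocampus it was 10 with the block, 101 with a residual component, 21 at an adjusted p under 0.1, 2 with the compared groups alone and 14 without WT number 3. In the P60 hippocampus it was 0 with the compared groups alone and 2 without number 1 of both genotypes. For the difference between E14 and the frontal cortex it was 1 and 1 with voom at P30 and P60 and 23 and 24 with no filter. For the interactions with age it was 2, 1 and 6 with no filter in the amygdala, frontal cortex and hippocampus.

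The number of lists called was 0 in each of the 7 settings with an estimated correlation, and with fry 2 in the P30 amygdala and 0 in the others. In the P30 frontal cortex it was 4 with the block, 3 with sex and 2 with a residual component, and in the P60 frontal cortex 6, 5 and 5. In the P60 hippocampus it was 0 with the block. Of 39 list calls 12 held without each replicate in turn and 27 were lost in at least 1 fit; 3 lists turned sign, namely the E14 cell cycle list without KO replicate 4 (0.0247) or KO replicate 5 (0.000763), the E14 ganglionic eminence list without KO replicate 4 (0.00634; -0.175 without WT replicate 4) and the P30 hippocampus excitatory neuron list without WT replicate 3 (-0.00800; 0.315 without WT replicate 1). Seed site shifts, region checks and region interactions stayed on their side of the threshold in the alternatives tried.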

Other observations

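Interferon-stimulated genes had a median above WT in 6 of 7 settings, and the difference between settings was not tested. At E14 all 9 tested members were higher in KO (median log2 fold change 0.32), with adjusted p = 0.494 with an estimated correlation. In the P30 amygdala 19 of 20 were lower (median -0.30), with adjusted p = 0.388 with an estimated correlation; without WT replicate 3 the median was -0.09, with 12 lower, and the call ended. In the P60 frontal cortex 16 of 20 were higher (median 0.19), with adjusted p = 0.896 with an estimated correlation; the call ended without KO replicate 4 (0.14), and the median was 0.12 without KO replicate 3. In the other 4 settings 14 of 20 were higher and the list was not called, with medians of 0.08 in the P30 frontal cortex, 0.08 in the P30 hippocampus, 0.15 in the P60 amygdala and 0.05 in the P60 hippocampus, and adjusted p = 0.982, 0.838, 0.734 and 0.949 with an estimated correlation.

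Of the genes tested at all 3 ages, 16 had an unadjusted p under 0.05 at each, 11 of them within 15 Mb of Mir146, against 0.899 expected in all if the ages were independent. Of the 5 outside that region 3 (Astn2, Syn2 and Slc17a7, chosen after their values were seen) changed sign between ages and 2 (Cdh23 and Gm5913) did not. Cdh23, a cadherin of sensory hair cells chosen after its values were seen, had log2 fold changes of -0.58 at E14, -0.22 at P30 and -0.56 at P60, in means of each animal number over regions.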
